A study of Mus musculus with 4 samples.

How the data were processed

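The data were 4 droplet-based single-cell RNA sequencing libraries (10x Genomics) of CD45+ CD8+ T cells sorted from mouse tumours. Per the labels, the tumours were grown from MB49, a mouse bladder carcinoma cell line, and the cells of 3 mice were pooled before each library was made. The WT and KO libraries came from subcutaneous tumours in mice aged 10 to 12 weeks, either wild type or with Bfar deleted in CD8+ T cells. The Young and Aged libraries came from tumours in Rag1-deficient hosts, which make no T or B cells of their own, aged 8 to 10 weeks. These hosts received CD8+ T cells of donors aged 8 weeks (Young) or 18 months (Aged) by vein on the day the tumour cells were inoculated. Groups were taken from the labels alone. Each group held 1 library, so no spread between replicates could be measured.

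The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, written by Cell Ranger per the file headers. The headers name Cell Ranger 6.1.1 for WT and KO and 7.1.0 for Young and Aged. The submitters' processing notes name Cell Ranger 6.0.0, Seurat 3.2.3 and the genome build mm10, so the version used is not settled by the sources used here. The annotation release, the setting for intronic reads and the calling of cell barcodes are not given in the sources used here. Per the labels, WT and KO were made with a 3' kit and Young and Aged with an immune profiling kit. Which version of the 3' kit was used is not settled by the sources used here. The sex-linked transcripts Xist and Ddx3y also set the pairs apart. Levels were therefore compared within a pair, KO with WT and Aged with Young, and never across pairs. All 4 files list the same 31253 genes.

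The files held 9746 barcodes and 85401443 UMIs for WT, 8665 and 72752583 for KO, 11060 and 68017515 for Young, and 9048 and 70727987 for Aged. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. This left 9405 WT, 8410 KO, 10538 Young and 8798 Aged cells, with median UMI totals of 6374, 6834.5, 4471.5 and 5687. Scrublet, as implemented in scanpy 1.11.5 with an expected doublet rate of 0.08, marked 0 WT, 0 KO, 1 Young and 0 Aged cells. A caller that marks so few cells of this many has not worked, and doublets should be regarded as still present. The 1 marked cell was removed, and removal of the 8% of cells with the highest scores was added as an alternative.

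Each pair was clustered on its own (Leiden, resolution 1, scanpy with igraph 0.11.9). The clustering used 2000 variable genes, 30 principal components and 15 neighbours, with no batch integration. Receptor segments, mitochondrial, ribosomal protein and sex-linked genes were left out of the variable genes. Both pairs gave 21 clusters. A cluster entered the CD8 T-like class if its CD3 and CD8 levels were at least 0.5 times those of the median cluster. It also needed no more markers of another class than of its own among its 10 leading genes. The markers were fixed before the data were examined, but this cutoff was set after they were seen. It kept 6 of the 21 clusters of the KO and WT pair out, with 292 of 8410 KO cells (3.47%) and 643 of 9405 WT cells (6.84%). In the other pair it kept 7 of 21 clusters out, with 460 of 8798 Aged cells (5.23%) and 1209 of 10537 Young cells (11.5%). The class was clustered again with the same settings, which gave 14 clusters per pair.

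UMIs were summed over the CD8 T-like cells of each library and expressed as counts per 1000000 UMIs of those cells (CPM). A level carries an exact 95% Poisson interval, a ratio of levels an exact conditional binomial interval, and a share of cells an exact (Clopper-Pearson) binomial interval. All of these cover counting error only, and none covers the variation between mice. No significance test was made across groups. The log2 ratio used a pseudocount of 1 CPM. A gene counted as measured with at least 20 UMIs over both libraries and at least 10 CPM in 1 of them.

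For each of 22 gene lists fixed before the data were examined, the median log2 ratio of the measured members was computed, with the numbers of members at least 1.5 times higher or lower. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, is given as a description of these libraries. Its 95% counting interval came from 500 Poisson resamples. Marker lists of 12 other cell types were treated the same way where at least 3 members were measured. Genes were named by a rule fixed before the data were examined. It takes Bfar, the 10 genes with the largest and the 10 with the smallest log2 ratio among genes with at least 20 CPM in 1 library and 50 UMIs over both, the highest and the lowest member of each list, and 12 genes chosen for shares of cells. From the 10 largest and smallest it leaves out receptor segments, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, unnamed gene models, markers of other cell types and genes over 5 times higher in the library's other cells.

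For shares of cells with at least 1 UMI of a gene, each cell was thinned at random to 2000 UMIs and shallower cells were left out. Tumour or epithelial-like cells served as the background, except for Bfar and Mki67, which they can express themselves. Correlations of log2 ratios between the pairs were taken across genes, which are not independent replicates. V beta usage was measured from UMIs of Trbv segments as the effective number of segments (inverse Simpson index), and each cell was also assigned to the segment with its most UMIs. Coordinates are those of GENCODE M21 on mm10, the build that the submitters' processing notes name.

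Ratios, their intervals, list percentiles and thinning were run on simulated data with known answers. Clustering and the class rule were not tested in this way. Poisson counts were drawn from the mean profile of each pair, with 200 genes changed by known folds. The draws held no variation between cells or mice, so the share of intervals that held 1 was largely set by the simulation. For KO versus WT, run on 7076 genes, the median recovered ratio was 2.01 at 2-fold and 1.50 at 1.5-fold, and 95.5% of unchanged genes had intervals that held 1. For Aged versus Young, run on 7618 genes, the values were 2.004, 1.51 and 95.3%. Of 100 unchanged lists, 6 and 3 lay outside the middle 95% of random lists. The unchanged lists were random genes, whereas members of a real list can move together, so this does not calibrate the percentiles of the real lists.

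The alternatives planned before the data were examined were TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios size factors, CPM without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, looser and stricter cell filters, no doublet removal, a gate on Cd8a or Cd8b1 and a CD3 gene in place of clusters, all cells, no cells with 3 or more UMIs of the G2 and M phase list, a pseudocount of 10 CPM, other minimum levels, other thinning depths, Leiden resolution 0.5 and V beta counted by cells. Added after the data were seen were removal of the cells with the highest Scrublet scores, removal of cells with a Mki67 UMI, equal weights of the T cell clusters in both libraries, and removal of cells assigned to Trbv12-1 or to no segment. The lists that open each comparison were also chosen after their values were seen.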

Results

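Single-cell transcriptomes of CD8+ T cells sorted from MB49 tumours were compared in a pair of experiments, each with 1 library per group and 3 mice pooled per library. The first set CD8+ T cells of mice that the labels give as deleted for Bfar in these cells (KO) against wild-type cells (WT). BFAR, the bifunctional apoptosis regulator, is a membrane protein of the endoplasmic reticulum with a RING domain. The second set CD8+ T cells of 18-month-old donors (Aged) against those of 8-week-old donors (Young) after transfer into Rag1-deficient hosts. Library totals ranged from 68017515 UMIs (Young) to 85401443 UMIs (WT). CD8 T-like cells made up 96.5% of the kept KO cells (95% interval 96.1 to 96.9) and 93.2% of the WT cells (92.6 to 93.7). They made up 94.8% of the Aged cells (94.3 to 95.2) and 88.5% of the Young cells (87.9 to 89.1). The sort for CD45 and CD8 can set these shares. Unless stated otherwise, intervals cover counting error only, and no difference below has a replicate check.

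The other cells in the KO and WT libraries were led by genes of mast cells or basophils (56 KO and 164 WT cells), of tumour or epithelial cells (52 and 272), of myeloid and dendritic cells (44 and 57), of NK cells (17 and 31) and of fibroblasts (6 and 38). A further cluster, led by Foxp3 and Il2ra, held 117 KO and 81 WT cells. In the Aged and Young libraries they were monocyte or macrophage-like (171 Aged and 324 Young cells), dendritic cell-like (100 and 365), fibroblast-like (131 and 234), tumour or epithelial-like (41 and 140), NK cell-like (14 and 97), plasmacytoid dendritic cell-like (2 and 14) and endothelial-like (1 and 35). The monocyte or macrophage-like cluster passed the cutoff of CD3 and CD8 levels (2810 and 1529 CPM) and was kept out by its markers alone. So were the KO and WT clusters of myeloid and dendritic genes (2024 and 975 CPM) and of Foxp3 (2461 and 964 CPM). These clusters carried T cell transcripts and may hold T cells or doublets. The levels reported from here on are those of the CD8 T-like cells.

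Bfar was the gene to check first, since the labels give it as deleted in the CD8+ T cells of the KO mice. It lies on chromosome 16 at positions 13671858 to 13703612 of the plus strand in mm10 (ENSMUSG00000022684), a protein-coding gene whose main transcript has 8 exons. The last exon runs from 13702065 to 13703612 and holds the 3' untranslated region from 13702255. The KO cells held 1478 Bfar UMIs, or 22.4 CPM (21.3 to 23.6), and the WT cells 2152 UMIs, or 32.3 CPM (30.9 to 33.7). The KO level was 0.694 times the WT level (0.649 to 0.742). In the other cells of the same libraries Bfar stood at 26.3 CPM in KO and 30.1 CPM in WT, a ratio of 0.875 (0.732 to 1.04). These cells are no reference without the deletion, since clusters that passed the cutoff of CD3 and CD8 levels are among them. Those clusters were the one led by Foxp3 (117 KO and 81 WT cells) and that of myeloid and dendritic genes (44 and 57). Transcripts were still counted in KO. Per the labels the kit reads the 3' end, and which exons were deleted is not given in the sources used here, so a tag outside the deleted part would not check the label. In the transfer experiment Bfar stood at 26.2 CPM (25.0 to 27.5) in Aged and 22.3 CPM (21.03 to 23.6) in Young cells, a ratio of 1.18 (1.09 to 1.27), or a log2 ratio of 0.22 that was 0.11 with equal cluster weights. The share of cells with a Bfar UMI after thinning was 4.55% in KO, 6.55% in WT, 5.398% in Aged and 4.37% in Young. Without thinning it was 15.6%, 19.9%, 16.6% and 11.03%. Tumour or epithelial-like cells can express Bfar themselves, so their shares (9.80%, 5.19%, 2.56% and 4.13%) give no background for it.

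The comparison of KO with WT asks how the Bfar deletion given in the labels marks tumour-infiltrating CD8+ T cells. In these libraries NK-type receptors and cytokines and chemokines stood higher in KO as groups, and naive and memory genes lower. However, 5 of 8, 15 of 17 and 16 of 18 members differed by less than 1.5 times. The medians moved with some alternatives, and that of NK-type receptors changed sign without a filter on low counts (-0.10). Genes of the type I interferon response stood slightly lower as a group, with none past 1.5 times. Ccl1, a chemokine that signals through CCR8, was 2.84 times higher in KO (141 against 49.6 CPM, interval of the ratio 2.73 to 2.96). Il2ra, the alpha chain of the high-affinity interleukin 2 receptor, was 1.66 times higher (1.60 to 1.74). Foxp3, which led a cluster outside the class together with Il2ra and Areg, had 160 UMIs in KO and 72 UMIs in WT inside the class. Klrc2, which encodes the activating receptor NKG2C, was 1.78 times higher (1.71 to 1.85). Gzmb, the main cytotoxic granzyme, was lower, at 639.9 CPM in KO and 1104 CPM in WT (ratio 0.580, 0.573 to 0.587).

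Of the 10 genes with the largest ratios, the others were Arrdc3 at 2.07, Nrgn at 1.93, Areg (the growth factor amphiregulin) at 1.84, Klri2 (an NK-type receptor) at 1.81, Slc15a3 at 1.74, Gzmf at 1.69 (58.3 against 34.5 CPM) and Gpr55 at 1.65. At the other end Fam241a had the smallest ratio, at 0.431 (31.5 against 73.1 CPM). It was followed by Cd38 at 0.571, Klf2 (a transcription factor of quiescent, recirculating T cells) at 0.577 (157 against 273 CPM), and Maf (a transcription factor of exhausted and interleukin 10-producing T cells) at 0.580. Gimap7 stood at 0.601, Abi3 at 0.617, Trib2 at 0.619, Dapl1 at 0.620 and Fdps, an enzyme of the mevalonate pathway, at 0.630. With equal weights of the T cell clusters in both libraries, an alternative added after the data were seen, none of the 20 genes changed direction. The log2 ratio then stood at 0.15 for Gzmf (0.74 without weights), 0.43 for Il2ra (0.72), 0.49 for Klri2 (0.81), 0.46 for Slc15a3 (0.76), -0.41 for Maf (-0.78), -0.39 for Gimap7 (-0.73) and -0.77 for Fam241a (-1.19).

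**Figure D1:**
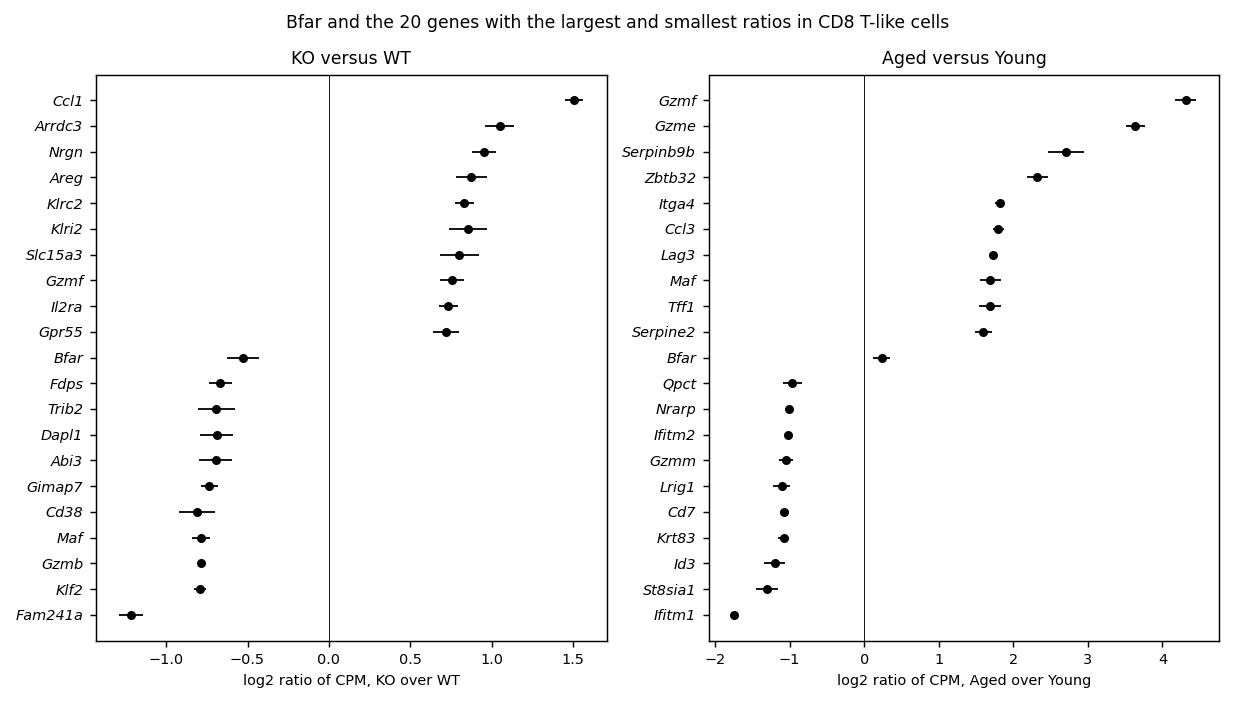
Log2 ratios of CPM in CD8 T-like cells (horizontal axis, no unit) for Bfar and the 20 genes with the largest and smallest ratios, KO over WT on the left and Aged over Young on the right, 1 library per group. Points are ratios of levels without a pseudocount and bars are exact 95% counting intervals. Ccl1 (2.84-fold) and Fam241a (0.431-fold) lie at the ends on the left, and Gzmf (19.8-fold) and Ifitm1 (0.298-fold) on the right.

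Among the fixed lists, NK-type receptors stood highest. The median log2 ratio of their 8 measured members was 0.40 (counting interval 0.39 to 0.42), at percentile 100 of random lists. Of the 8 members, 2 were at least 1.5 times higher, 1 was at least 1.5 times lower and 5 lay between, with Klrc2 highest and Fcer1g, a signalling adaptor also abundant in myeloid and NK cells, lowest at 0.553 (6.22 against 11.2 CPM). Cytokines and chemokines had a median of 0.17 over 17 members (percentile 100), with 2 at least 1.5 times higher and none lower. Ifng, the gene of interferon gamma, was at 178 CPM in KO and 158 CPM in WT (1.12, 1.09 to 1.15; a log2 ratio of 0.17, or -0.0014 with equal cluster weights), and Xcl1 was lowest of that list at 0.919. Short-lived effector genes had a median of 0.11 (percentile 100), with S100a4 highest at 1.44 and Klf2 lowest. With equal cluster weights the medians were 0.20 for NK-type receptors, 0.042 for cytokines and chemokines and -0.019 for short-lived effector genes. Without a filter on low counts the median of NK-type receptors was -0.10.

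The type I interferon response list lay lowest, with a median of -0.18 (-0.20 to -0.15) over 36 members, at percentile 0. None of its members differed by 1.5 times in either direction. Isg15, a ubiquitin-like protein induced by interferon, was lowest of the list at 0.693 (198 against 285 CPM) and Parp14 highest at 1.04. This median was -0.029 with equal cluster weights. Naive and memory genes had a median of -0.13 over 18 members (percentile 0), with 2 at least 1.5 times lower and none higher. The list held both Klf2 at 0.577 and Il7r, the interleukin 7 receptor, at 1.27 (1.25 to 1.29). With equal cluster weights the median was -0.072 and the log2 ratio of Il7r 0.13 (0.34 without weights). The cell cycle G2 and M phase list stood at -0.18 over 28 members (percentile 0), with Ube2c lowest at 0.660 and Hmgb2 highest at 1.16. Its median was -0.0067 with equal cluster weights.

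Inhibitory receptors stood slightly lower in KO as a group, and exhaustion transcription factors within the range of random lists. The inhibitory receptors had a median of -0.0999 (-0.15 to -0.036) over 12 members (percentile 2.33), none of which differed by 1.5 times, and -0.12 with equal cluster weights. Pdcd1, which encodes PD-1, stood at 331 CPM in KO and 310.3 CPM in WT (1.07, 1.05 to 1.09) and Havcr2, which encodes TIM-3, at 65.8 and 65.5 CPM (1.01, 0.964 to 1.05). Ctla4 was lowest of the list at 0.718 (0.705 to 0.731) and Cd101 highest at 1.39. In all cells that passed the filters the median of the list was 0.067. Exhaustion transcription factors had a median of 0.021 (percentile 89.1), with Nr4a1 highest at 1.34 and Maf lowest. Tcf7, a transcription factor of memory and progenitor T cells, was at 93.2 CPM in KO and 93.4 CPM in WT (0.997, 0.963 to 1.03). The cytotoxic effector list had a median of -0.029 (percentile 34.05), with Gzmf at 1.69 and Gzmb at 0.580 at its ends. Gzmk, a granzyme of memory and early exhausted CD8+ T cells, was at 0.732 (0.710 to 0.754), a log2 ratio of -0.45 that was -0.052 with equal cluster weights.

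Of the remaining lists, the tissue residency, mitochondrially encoded and immediate early lists lay outside the middle 95% of random lists. Tissue residency genes stood at 0.071 (percentile 99.6), mitochondrially encoded genes at 0.095 (99.5), immediate early and heat shock genes at 0.039 (98.8, with Atf3 highest at 1.73, and -0.059 as its log2 ratio in all cells), costimulation and activation receptors at 0.029 (94.98) and apoptosis regulators at 0.0056 (90.8, with Bcl2a1d highest at 1.46 and Bfar lowest). JAK-STAT components stood at -0.015 (70.9), age-associated and virtual memory genes at -0.011 (59.4), chemokine and trafficking receptors at -0.034 (31.6, with Ccr2 highest at 1.44) and the unfolded protein response at -0.059 (9.59). The S phase list stood at -0.075 (9.09), interferon gamma and antigen presentation at -0.048 (6.90), oxidative phosphorylation at -0.032 (6.13) and glycolysis at -0.060 (5.95). The median of all 7161 measured genes was -0.039. The medians of tissue residency and of immediate early genes were, with equal cluster weights, -0.043 and -0.011. Signs also changed for costimulation and activation receptors (-0.060), apoptosis regulators (-0.0044), the S phase list (0.021) and age-associated and virtual memory genes (0.075). The log2 ratios of the genes at the ends of the lists moved too, to 0.25 for S100a4 (0.52 without weights), 0.24 for Nr4a1 (0.42), 0.29 for Cd101 (0.47), 0.45 for Atf3 (0.77), -0.36 for Ube2c (-0.59), -0.22 for Xcl1 (-0.12) and 0.13 for Parp14 (0.060). The marker list of NK cells stood at -0.17 over 4 members and that of plasmacytoid dendritic cells at 0.053 over 3. The lists of the other cell types had fewer than 3 measured members.

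**Figure D2:**
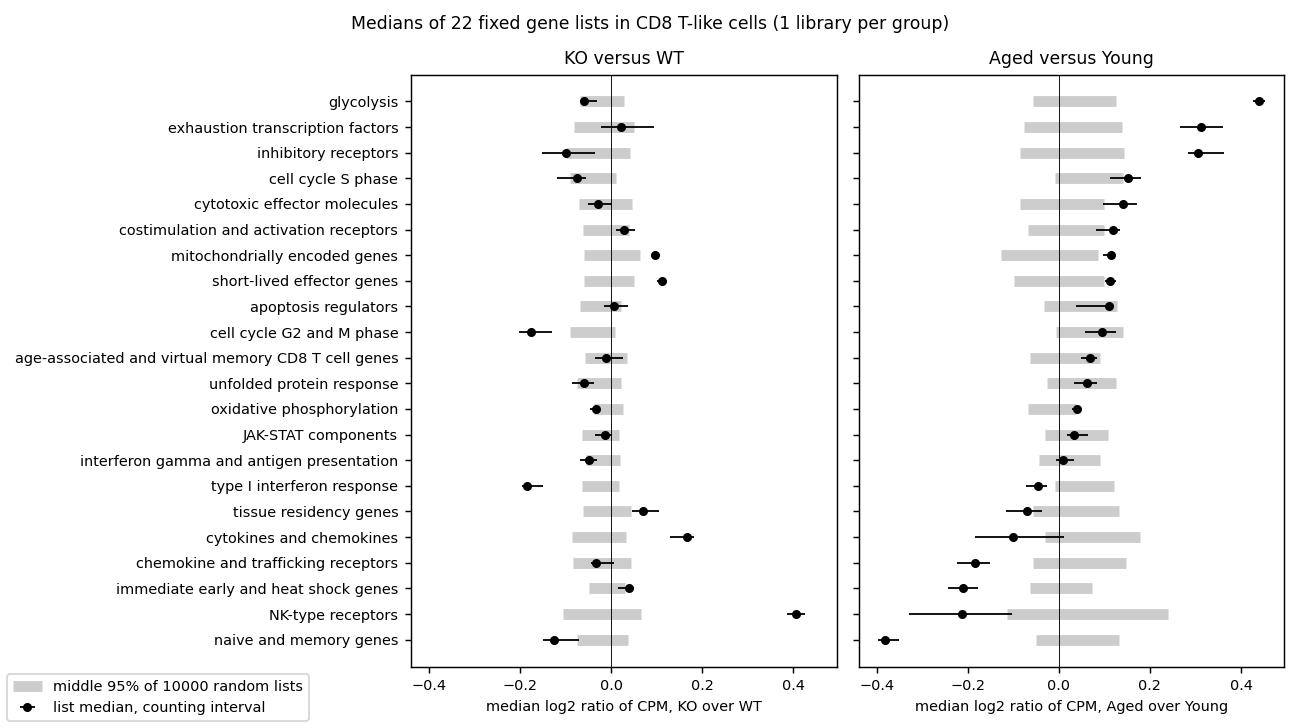
Median log2 ratio of CPM (horizontal axes, no unit) of the 22 fixed gene lists in CD8 T-like cells, KO over WT on the left and Aged over Young on the right. Black points and bars are medians with 95% counting intervals, and grey bars span the middle 95% of 10000 random lists of the same size and expression. NK-type receptors stand at 0.40 on the left and -0.21 on the right, and glycolysis at -0.060 on the left and 0.44 on the right.

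Shares of cells with a UMI, after each cell was thinned to 2000 UMIs, were taken at equal depth. Left out as shallower were 69 KO and 99 WT cells, and median depths before thinning were 6762 and 6189.5 UMIs. Gzmb was seen in 36.1% of KO cells (35.0 to 37.2) and 42.4% of WT cells (41.4 to 43.4), or 50.7% and 56.0% without thinning. The background in tumour or epithelial-like cells was 5.88% of 51 KO cells and 10.7% of 270 WT cells, whose median depths were 45901.5 and 40683.5 UMIs. Gzmk was seen in 17.4% of KO and 22.2% of WT cells (33.7% and 39.1% without thinning, background 0 of 51 cells and 1.85%). Cx3cr1, a receptor of effector cells, was seen in 8.08% and 5.67% (19.1% and 13.4% without thinning, background 3.92% and 0.741%), and since 2 of 51 background cells allow up to 13.5%, the KO share cannot be set apart from background. Cxcr6 was seen in 41.4% and 37.7% (69.8% and 63.7%, background 13.7% and 5.19%), and Pdcd1 in 38.9% and 38.5% (63.3% and 62.7%, background 7.84% and 5.56%). Mki67, a marker of cycling cells, was seen in 5.12% and 5.68% (11.9% and 12.4%). Tumour or epithelial-like cells can express Mki67 themselves, so their shares (11.8% and 13.0%) give no background for it.

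Different T cell clusters held the largest parts of the class in the libraries. The largest in KO was led by Gzma and Csf1 (13.0% of KO and 10.0% of WT cells). The largest in WT was led by Maf and Gzmk (15.9% of WT and 8.61% of KO cells). A cluster led by Gzmd, Gzmf and Prf1 held 5.395% of KO and 2.23% of WT cells. This last cluster met the rule for a terminally exhausted-like name with 3 markers, the fewest that the rule allows. These sizes are given to place the levels above and are not a separate result, because the genes that define the clusters also differed between the libraries.

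The comparison of Aged with Young asks how donor age marks CD8+ T cells in the same kind of tumour. In these libraries inhibitory receptors, transcription factors of exhaustion and glycolysis stood higher in Aged as groups, and naive and memory genes lower. Not every member moved that way, and in glycolysis, exhaustion factors and naive and memory genes most members differed by less than 1.5 times. Lag3, an inhibitory receptor that binds MHC class II, was 3.31 times higher in Aged (190 against 57.3 CPM, interval of the ratio 3.18 to 3.45). Havcr2 was 2.70 times higher (2.58 to 2.83), Ctla4 2.60 times (2.53 to 2.68) and Pdcd1 1.91 times (1.87 to 1.95). Tcf7 was lower, at 77.4 CPM in Aged and 132 CPM in Young (0.588, 0.567 to 0.610). The log2 ratio was -0.35 for Tcf7 (-0.76 without weights) and 0.54 for Pdcd1 (0.93) with equal cluster weights.

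The largest ratios belonged to granzymes that are not part of the usual cytotoxic pair. Gzmf was 19.8 times higher in Aged (164 against 8.28 CPM, 18.0 to 21.9) and Gzme 12.4 times higher (132 against 10.6 CPM, 11.4 to 13.6). Of the Aged UMIs of Gzmd, Gzme and Gzmf, 97.54% lay in a single T cell cluster of 374 cells, and of its 364 cells with a V beta segment 84.6% carried Trbv12-1. Gzmd was chosen after its values were seen. Among the genes that the naming rule allows, which leaves out Gzmd, next came Serpinb9b at 6.52 and Zbtb32 (a transcriptional repressor of activated lymphocytes) at 4.98. Itga4 (the alpha chain of the integrin VLA-4) stood at 3.52, Ccl3 (a chemokine of activated T cells) at 3.48, Maf at 3.23, Tff1 at 3.22 and Serpine2 at 3.02. Without the cells assigned to Trbv12-1 or to no segment, an alternative added after the data were seen, the log2 ratios of Gzmf, Gzme, Serpinb9b and Serpine2 turned to -0.68, -0.80, -1.26 and -0.25. This removal takes out most cells of the granzyme cluster in Aged but not in Young, where 70.9% of them carried Trbv19, so a fall of the granzyme ratios is built into it. Serpine2 also led that cluster, so the same holds for its ratio. Itga4, Ccl3, Lag3, Maf, Zbtb32 and Tff1 kept their direction, with Tff1 at 0.77 (1.58 in all cells of the class). Zbtb32 stood at 1.18 (2.20) and Ccl3 at 1.10 (1.77) with equal cluster weights.

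At the other end lay Ifitm1, an interferon-induced membrane protein, at 0.298 (276 against 928 CPM, 0.292 to 0.303). St8sia1 stood at 0.406, Id3 (a transcription factor of memory precursors) at 0.436, Lrig1 at 0.464, Krt83 at 0.473 and Cd7 at 0.477. Gzmm stood at 0.483, Ifitm2 at 0.492, Nrarp (a target of Notch signalling) at 0.497 and Qpct at 0.513. With equal cluster weights the log2 ratio was -0.81 for Ifitm1 (-1.74 without weights), -0.73 for St8sia1 (-1.21), -0.70 for Id3 (-1.12), -0.64 for Krt83 (-1.06), -0.62 for Gzmm (-1.02) and -0.30 for Ifitm2 (-1.02). Itgae, which encodes the CD103 chain of a tissue residency integrin, had few transcripts in both libraries and was lower in Aged, at 3.28 against 17.5 CPM (0.187, 0.160 to 0.218).

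As groups, inhibitory receptors had a median log2 ratio of 0.31 (0.28 to 0.36) over 11 members, at percentile 100 of random lists. Of these 11 members, 5 were at least 1.5 times higher, 1 (Pdcd1lg2, at 0.635) was lower and 5 lay between. Pdcd1lg2 encodes a ligand of PD-1 and not a receptor, although the fixed list holds it. Exhaustion transcription factors also stood at 0.31 (0.27 to 0.36) over 13 members, at percentile 100, with 4 higher, 1 lower and 8 between. Maf was highest of them and Nr4a1, an immediate early gene of receptor signalling, lowest at 0.545 (0.531 to 0.559). Glycolysis had a median of 0.44 (0.43 to 0.45) over 20 members, at percentile 100, with 5 at least 1.5 times higher and none lower, from Slc2a1 at 0.965 to Slc2a3, a glucose transporter, at 2.22 (a log2 ratio of 1.12, or 0.72 with equal cluster weights). With equal cluster weights the median of the exhaustion transcription factors was 0.13, and among genes of at least 50 CPM it was 0.079. The median of all 7798 measured genes was 0.086.

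Naive and memory genes lay lowest, with a median of -0.38 (-0.40 to -0.35) over 18 members, at percentile 0. Of these, 3 were at least 1.5 times lower, 1 was higher and 14 lay between, with Id3 lowest and Cd27 highest at 1.70. The median was -0.16 with equal cluster weights, and the log2 ratio of Cd27 0.47 (0.76 without weights). Immediate early and heat shock genes stood at -0.21 over 31 members (percentile 0), with 2 lower and none higher, and Zfp36l1 lowest at 0.593. Chemokine and trafficking receptors stood at -0.18 (percentile 0.010), with Itga4 highest and Ccr8 lowest at 0.507, and NK-type receptors at -0.21 over 7 members (percentile 0.290), with Klrc2 at 1.03 and Fcer1g at 0.328 at the ends. Immediate early genes stood at -0.13 and trafficking receptors at -0.11 with equal cluster weights.

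The cytotoxic effector list had a median of 0.14 over 17 members (percentile 99.7), with 6 at least 1.5 times higher and 2 lower. Gzmb was at 2063 CPM in Aged and 1069.7 CPM in Young (1.93, 1.91 to 1.95) and Gzmk at 447 and 310 CPM (1.44, 1.42 to 1.47; a log2 ratio of 0.53, or 0.22 with equal cluster weights). Without the cells assigned to Trbv12-1 or to no segment, a removal that takes out most of the granzyme cluster in Aged, the median of the list was -0.15. With equal cluster weights it was 0.085. Cytokines and chemokines stood at -0.10 over 17 members (percentile 0.090), with 3 higher and 2 lower, from Tnfsf11 at 0.532 to Ccl3. Ifng was 1.29 times higher (1.26 to 1.32; a log2 ratio of 0.37, or 0.20 with equal cluster weights). This median changed sign among genes of at least 50 CPM (0.0999) and without cells that held a Mki67 UMI (0.036).

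Of the other lists, S phase stood at 0.15 (percentile 98.7), costimulation and activation receptors at 0.12 (99.2, with Tnfrsf4, which encodes OX40, highest at 2.70 and Cd83 lowest at 0.337), mitochondrially encoded genes at 0.11 (99.1), short-lived effector genes at 0.11 (98.8, with Itgb1 lowest at 0.586) and apoptosis regulators at 0.11 (93.4). G2 and M phase stood at 0.095 (76.7), age-associated and virtual memory genes at 0.069 (92.7, with 7 of 24 members at least 1.5 times higher and none lower), the unfolded protein response at 0.062 (61.4, with Asns highest at 3.21) and oxidative phosphorylation at 0.040 (98.0). JAK-STAT components stood at 0.034 (44.1, with Il10ra, the interleukin 10 receptor, highest at 2.54, a log2 ratio of 1.33 that was 0.70 with equal cluster weights), interferon gamma and antigen presentation at 0.0089 (35.0, with Irf8 highest at 1.95, a log2 ratio that turned to -0.25 without the cells assigned to Trbv12-1 or to no segment, and Cxcl10 lowest at 0.553), type I interferon response at -0.046 (0.190) and tissue residency genes at -0.070 (1.41). With equal cluster weights S phase stood at 0.076, costimulation receptors at 0.049, G2 and M phase at 0.0019, apoptosis regulators at 0.0019, the unfolded protein response at 0.0090 and oxidative phosphorylation at 0.010. Oxidative phosphorylation turned to -0.031 with TMM scaling and the type I interferon response to 0.048 in all cells. A fall of Irf8, a leading gene of the granzyme cluster, is built into the removal by segment, which takes out most of that cluster in Aged. Among markers of other cell types, those of erythroid cells stood at 3.41 over 4 members, those of plasmacytoid dendritic cells at 0.28 over 3, those of dendritic cells at -0.077 over 3, those of monocytes or macrophages at -0.11 over 3 and those of NK cells at -0.53 over 4.

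After thinning, which left out 390 Aged and 640 Young cells (median depths 5606.5 and 4363 UMIs), Pdcd1 was seen in 41.8% of Aged (40.7 to 42.9) and 27.9% of Young cells (26.9 to 28.8). Without thinning the shares were 61.2% and 42.0%. The background in tumour or epithelial-like cells was 10.3% of 39 Aged and 13.2% of 121 Young cells, with median depths of 31656 and 6912.5 UMIs. Havcr2 was seen in 16.2% and 7.12% (34.4% and 15.2% without thinning, background 5.13% and 4.96%), and Gzmb in 72.3% and 55.4% (82.8% and 67.3%, background 7.69% and 25.6%). Tcf7 was seen in 15.04% and 22.9% (29.2% and 39.6%, background 2.56% and 5.79%), and Itgae in 0.805% and 2.97% (1.87% and 5.75%, background 0 of 39 cells and 0.826%). The Itgae background allows up to 9.03% in Aged and 4.52% in Young, and the Havcr2 background up to 17.3% and 10.5%, so these shares cannot be set apart from background. Mki67 was seen in 10.2% and 9.27% (19.3% and 16.3%), with no background given by tumour or epithelial-like cells (10.3% and 24.0%) for the reason above.

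**Figure D3:**
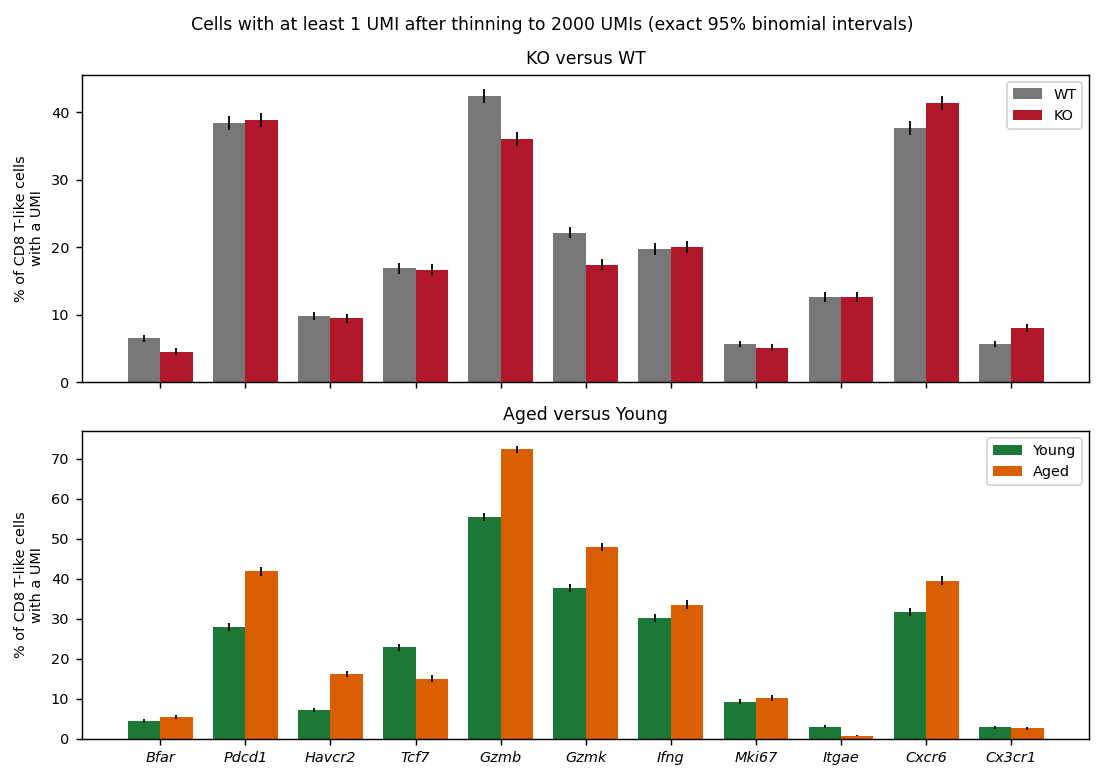
Percent of CD8 T-like cells with at least 1 UMI of the genes shown after each cell was thinned to 2000 UMIs (vertical axes), WT and KO above, Young and Aged below. Bars start at 0 and lines are exact 95% binomial intervals. Gzmb is seen in 42.4% of WT and 36.1% of KO cells and in 55.4% of Young and 72.3% of Aged cells.

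The clusters that held most of the class differed here too. The largest in Aged, a terminally exhausted-like cluster led by Maf, Lag3, Ctla4, Tox and Havcr2, held 21.05% of Aged and 0.976% of Young cells and so came almost wholly from 1 library. The largest in Young, led by Ccl5 and Klf3, held 20.8% of Young and 12.8% of Aged cells and met the rule for a naive or central memory-like name with 3 markers, the fewest that the rule allows. A cluster led by Ifitm1 and Itgae held 14.9% of Young and 6.42% of Aged cells. As above, these sizes only place the levels, since their defining genes differed.

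Setting the experiments side by side asks whether genes that differ between KO and WT also differ between Aged and Young. Across the 6892 genes measured in both pairs, the log2 ratios had a Pearson r of -0.21 and a Spearman rho of -0.27. In 41.0% of genes the log2 ratio lay on the same side of the pair's median in both pairs. The pairs share no library. In all cells that passed the filters r was 0.23 with a rho of -0.0068. The sign of r thus depends on which cells are summed, while by ranks the relation nearly vanished without turning. Genes on opposite sides included Maf (0.580 in KO over WT, 3.23 in Aged over Young), Ctla4 (0.718 and 2.60), Gzmb (0.580 and 1.93) and Bfar (0.694 and 1.18). Gzmf was higher in both (1.69 and 19.8), and Tcf7, Pdcd1 and Havcr2 stood within 1.07 times of each other in KO and WT.

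V beta usage was the last comparison, and shows how evenly the pooled T cells with a Trbv UMI used their receptor segments. By Trbv UMIs the effective number of segments was 10.9 in KO (10.3 to 11.4) and 9.67 in WT (9.16 to 10.1), from 2001 and 2126 UMIs. With the 3' kit, these UMIs came from only 1664 of 8118 KO and 1719 of 8762 WT cells of the class. Most KO and WT cells thus gave no segment. The effective number was 10.2 in Aged (10.1 to 10.3) and 11.5 in Young (11.4 to 11.5), from 83184 and 71162 UMIs. The latter UMIs came from 7710 Aged and 8634 Young cells, and UMIs of the same cell are not independent. The intervals of values and shares by UMIs are therefore too narrow. By cells, the effective number was 8.61 (8.30 to 8.91) in Aged and 10.04 (9.80 to 10.3) in Young. In WT, Trbv12-2 was the most used segment (18.4%, 16.8 to 20.1). In KO, Trbv12-2 (15.2%, 13.6 to 16.8) and Trbv13-1 (14.7%, 13.2 to 16.4) could not be ranked, with 257 and 258 cells when counted by cells. In Aged, Trbv12-1 took 20.1% of the UMIs (19.8 to 20.3), against 10.8% in Young (10.6 to 11.1). Counted by cells, Trbv12-1 took 26.5% of the Aged cells with a segment, and Trbv26 was most used in Young, with 17.3%. By UMIs the leading Young segments were instead Trbv16 (12.5%, 12.3 to 12.8) and Trbv12-2 (12.4%, 12.2 to 12.7).

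**Figure D4:**
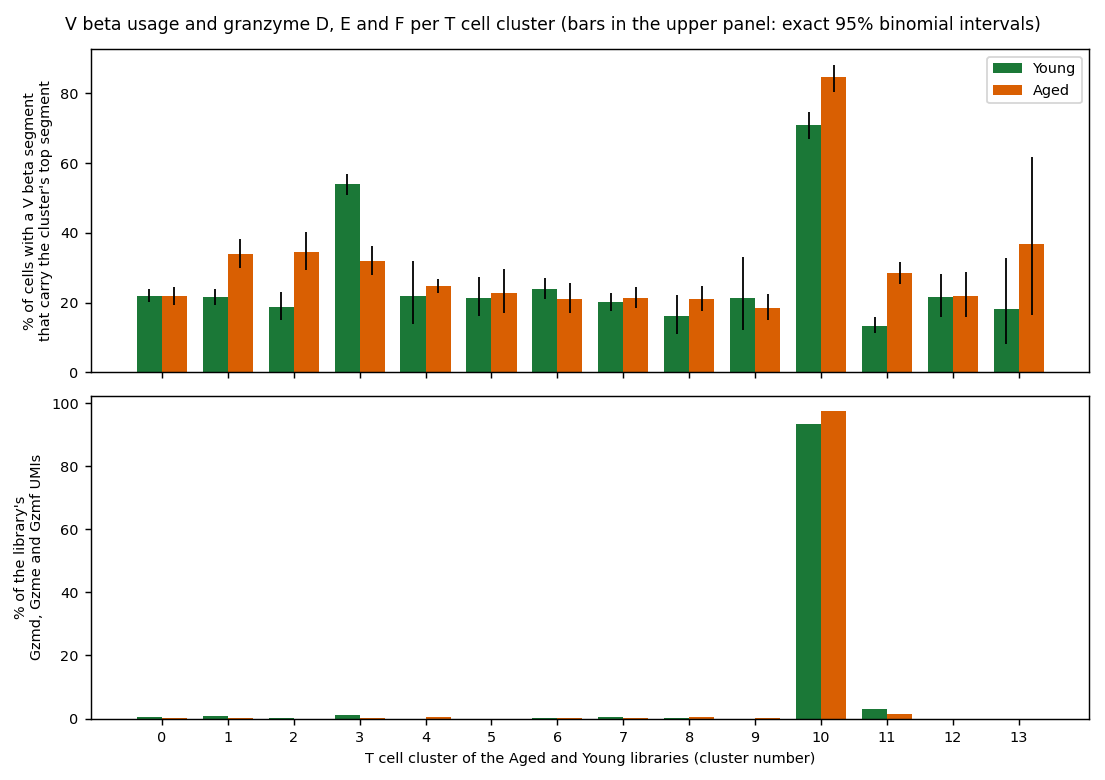
Upper panel, percent of the cells with a V beta segment that carry the most used segment of their cluster (vertical axis), for the 14 T cell clusters of the Young and Aged libraries, with exact 95% binomial intervals. Lower panel, percent of each library's Gzmd, Gzme and Gzmf UMIs found in each cluster. Cluster 10 stands out in both panels, with 84.6% Trbv12-1 in Aged and 70.9% Trbv19 in Young.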

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

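Of the tests in this part, those of V beta segments and of RNA from other cells on the granzymes, and those of cluster shares and of RNA from other cells on the KO to WT ratios, were chosen after the result was seen. The rule by which the test of cluster shares was read was also changed after its value was seen. The test of V beta segments inside the granzyme cluster replaced removals by segment after their values were seen. The tests on inhibitory receptors were written before their values were seen.

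Some signals lie in transcripts that the comparisons did not use, each above the 3 counts that a count of 0 allows. The WT library held 52 UMIs of Ddx3y, a gene of the Y chromosome, in 13 cells, none of them CD8 T-like, while 91.7% of its cells carried Xist, the transcript of the inactive X chromosome. The KO library held 0 Ddx3y UMIs. No explanation was tested.

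The Aged library held 2512 UMIs of the haemoglobin gene Hbb-bs in 8 cells, 7 of them CD8 T-like, against 64 UMIs in 6 cells of the Young library. These few cells set the median of the erythroid markers in Aged over Young (3.41). The Aged library also held 483 UMIs of Cd4 in 247 cells, 235 of them CD8 T-like, against 78 UMIs in 45 cells of the Young library. Of the 228 such CD8 T-like cells with a V beta segment, 74.1% (67.9 to 79.7) were assigned to Trbv12-1, against 25.1% (24.1 to 26.1) of the Aged cells without a Cd4 UMI. A Cd8b1 UMI was seen in 98.3% of the 235 cells and in 92.8% of the others, without thinning and with no background share, and the cells with a Cd4 UMI were deeper (median 7188 against 5575 UMIs).

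The KO library held 605 UMIs of Foxp3, a transcription factor of regulatory T cells, in 145 cells, and the WT library 276 UMIs in 89 cells. Of these cells, 42 in KO and 25 in WT were in the CD8 T-like class, with 160 and 72 UMIs. No biological explanation was tested for these transcripts.

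The pattern of Gzmd (chosen after its values were seen), Gzme and Gzmf in Aged over Young was weighed because of its size, a median log2 ratio of 4.03 (3.90 to 4.16). RNA of other cells is argued against, since the smallest difference of the 3 genes equals 68.5% of their level in the other cells. Whether more cells of a granzyme cluster could give the pattern depends on the clustering and stays open. When all kept cells were clustered, a cluster led by Gzmf, Gzme and Gzmd held 13.2% of Aged and 0.693% of Young cells. In the same clustering, a cluster led by Slc16a11 and Galnt18 held 3.66% of Young and 0.0682% of Aged cells. When the CD8 T-like cells were clustered alone, the cluster led by Gzmd, Gzmf and Gzme held 4.49% of Aged and 6.08% of Young cells. That clustering left Gzmf at 4.37 with equal cluster weights (4.15 without). Slc16a11 was also among the leading genes of its granzyme cluster. Whether that cluster joined cells of both clusters above was not tested. Inside that cluster the median was 4.53 (3.42 to 6.15 over resampled cells) for the 308 Aged cells of Trbv12-1 over the Young cells, but 1.36 (-0.75 to 3.34) for the 56 Aged cells of other segments. With so few cells, a single receptor that may have come from 1 of the pooled mice cannot be told apart from a difference across the cluster. The medians without the cells of Trbv12-1 (-0.68), of Trbv12-1 and Trbv19 (-0.35) or of the whole cluster (1.71) decide nothing, because these removals take out most granzyme-bearing cells, and an effect of donor age stays open and untested.

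For inhibitory receptors in Aged over Young, with a median log2 ratio of 0.31 (0.28 to 0.36), 3 explanations were weighed. The same cells with Trbv12-1 are argued against as the whole cause, since the median was 0.39 (0.32 to 0.45) without them. After each cell was thinned to 2000 UMIs the median was 0.40 (0.34 to 0.46). This argues against a greater weight of deeper cells in the sums. It decides nothing else on unequal depth, since thinning leaves the expected CPM of each cell unchanged. Without the terminally exhausted-like cluster, which held 21.05% of Aged and 0.976% of Young cells, the median was 0.26 (0.20 to 0.32). That interval leaves open whether this cluster could carry a part of the difference, and an effect of donor age or of the single mice pooled stays open.

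For the 20 genes with the largest and smallest KO to WT ratios, RNA of other cells is argued against. All 20 genes differed by more than the level in the other cells times the share of their RNA, 0.134% in KO and 0.312% in WT as estimated from 55 abundant genes of those cells. The gene with the smallest need would take a share of 7.78%, a need kept high in part by the naming rule, which leaves out genes over 5 times higher in the other cells. The low measured share is therefore what decides. The 55 genes behind it were themselves chosen as far higher in the other cells than in the CD8 T-like cells, which caps that share in advance. With equal weights of the T cell clusters the genes kept a median of 70.0% of their log2 ratios (61.3 to 79.5). This interval comes from the ranked values of the 20 genes, which are not independent, and does not cover counting error. Changes inside clusters and different shares of clusters cannot be told apart by this, because the clusters are themselves defined by genes that differed, and an effect of the Bfar deletion given in the labels may lie in either.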

How the results depend on the processing

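The alternatives with equal weights of the T cell clusters, without cells that held a Mki67 UMI, without the cells with the highest Scrublet scores and without the cells assigned to Trbv12-1 or to no segment were tests chosen after the data were seen; the others were planned. No paired analysis was possible because each group had 1 library. Over 2711 values under alternatives, 1514 stayed within the counting interval, 1161 moved beyond it with the same direction or without one called, and 36 of called values changed sign. Unless stated, the cause was not tested for any change given here. No scaling moved the median log2 ratio of all genes by more than 0.1, the largest shifts being 0.039 in KO over WT (TMM) and -0.080 in Aged over Young (median-of-ratios).

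The Bfar log2 ratio kept its direction under the alternatives run for it, from -0.52 to -0.22 in KO over WT and from 0.15 to 0.65 in Aged over Young. With equal cluster weights, not part of these ranges, it was -0.519 and 0.11, and removal of the cells of Trbv12-1 or no segment was not run for Bfar. Direction was also kept in Aged over Young by inhibitory receptors (0.23 to 0.55), exhaustion transcription factors (0.079 to 0.61), glycolysis (0.27 to 0.45) and naive and memory genes (-0.46 to -0.045), and in KO over WT by cytokines and chemokines (0.042 to 0.21) and the type I interferon response (-0.40 to -0.029). NK-type receptors in KO over WT ranged from -0.10 to 0.58. The V beta effective numbers of KO (10.6 to 10.9) and WT (9.66 to 9.67) stayed within their intervals.

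Under TMM scaling the KO over WT medians were 0.44 for NK-type receptors, 0.21 for cytokines and chemokines and -0.14 for the type I interferon response. Those of Aged over Young were 0.24 for exhaustion transcription factors, 0.37 for glycolysis, 0.24 for inhibitory receptors, -0.45 for naive and memory genes and -0.031 for oxidative phosphorylation, which changed sign. Median-of-ratios size factors gave 0.44 for NK-type receptors and 0.20 for cytokines and chemokines in KO over WT. In Aged over Young they gave 0.23 for exhaustion transcription factors, 0.36 for glycolysis, 0.23 for inhibitory receptors, -0.46 for naive and memory genes and -0.041 for oxidative phosphorylation, again with a changed sign.

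The mean of per-cell CPM gave 0.43 for NK-type receptors and 0.090 for cytokines and chemokines in KO over WT. In Aged over Young it gave 0.40 for exhaustion transcription factors, 0.34 for glycolysis, 0.37 for inhibitory receptors and -0.21 for naive and memory genes. Changed signs were 0.021 for cytokines and chemokines, -0.013 for cytotoxic effector molecules, -0.0027 for oxidative phosphorylation and 0.046 for the type I interferon response.

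With cells chosen by gate, KO over WT stood at 0.49 for NK-type receptors, 0.090 for cytokines and chemokines and -0.14 for the type I interferon response. Aged over Young stood at 0.38 for exhaustion transcription factors, 0.38 for glycolysis, 0.41 for inhibitory receptors, -0.30 for naive and memory genes and, with a changed sign, 0.0099 for the type I interferon response. In all cells that passed the filters, KO over WT stood at 0.58 for NK-type receptors and -0.084 for the type I interferon response, and changed sign for Atf3 (-0.059), immediate early and heat shock genes (-0.10) and inhibitory receptors (0.067). Aged over Young stood at 0.38 for exhaustion transcription factors, 0.34 for glycolysis, 0.43 for inhibitory receptors and -0.27 for naive and memory genes, and changed sign for the type I interferon response (0.048). The Pearson correlation between the pairs turned to 0.23, with a Spearman rho of -0.0068. By construction this setting adds the other cell types, whose numbers differed between libraries.

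Without cells that held 3 or more UMIs of the G2 and M phase list, only 203 KO, 399 WT, 893 Aged and 1422 Young cells were left. This is therefore not a removal of cycling cells. Hmgb2 held 49.5% of the list's UMIs in KO, 43.3% in WT, 31.5% in Aged and 33.1% in Young. KO over WT stood at -0.22 for Bfar, 0.46 for NK-type receptors and -0.40 for the type I interferon response, with changed signs for Areg (-0.31), Gzmf (-3.34) and Ube2c (1.05). Aged over Young stood at 0.65 for Bfar, 0.61 for exhaustion transcription factors, 0.27 for glycolysis, 0.45 for inhibitory receptors and -0.045 for naive and memory genes. Its changed signs were Cxcl10 (0.33), cytokines and chemokines (0.22), cytotoxic effector molecules (-0.045), immediate early and heat shock genes (0.034), oxidative phosphorylation (-0.12) and the type I interferon response (0.089). The correlation was -0.064. Without cells that held a Mki67 UMI, cytokines and chemokines stood at 0.11 in KO over WT and at 0.036, with a changed sign, in Aged over Young, where glycolysis stood at 0.39 and naive and memory genes at -0.27.

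With equal weights of the T cell clusters, KO over WT stood at 0.20 for NK-type receptors, 0.042 for cytokines and chemokines and -0.029 for the type I interferon response. Of the called lists, immediate early and heat shock genes (-0.011), short-lived effector genes (-0.019) and tissue residency genes (-0.043) changed sign. Aged over Young stood at 0.13 for exhaustion transcription factors, 0.31 for glycolysis and -0.16 for naive and memory genes. Without the cells assigned to Trbv12-1 or to no segment, Aged over Young stood at 0.41 for exhaustion transcription factors, 0.386 for glycolysis, 0.386 for inhibitory receptors and -0.24 for naive and memory genes. Signs changed for Gzme (-0.80), Gzmf (-0.68), Irf8 (-0.25), Serpinb9b (-1.26), Serpine2 (-0.25), cytotoxic effector molecules (-0.15), oxidative phosphorylation (-0.0056) and the type I interferon response (0.096). For Gzme and Gzmf this follows from the construction, which removes most of their cluster in Aged and less of it in Young. Serpine2 and Irf8 also led that cluster, so a fall of their ratios is built in as well. The cytotoxic list holds granzymes of that cluster, so its change of sign decides nothing either.

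Among genes of at least 50 CPM, the type I interferon response stood at -0.12 in KO over WT. In Aged over Young exhaustion transcription factors stood at 0.079, inhibitory receptors at 0.55 and cytokines and chemokines, with a changed sign, at 0.0999. The correlation was -0.18. With no filter on low counts, KO over WT stood at 0.11 for cytokines and chemokines, -0.20 for the type I interferon response and -0.10, with a changed sign, for NK-type receptors, since members with few counts enter the median by construction. Aged over Young stood at 0.40 for exhaustion transcription factors, 0.26 for inhibitory receptors and, with a changed sign, 0.035 for cytokines and chemokines. A pseudocount of 10 CPM gave -0.38 for Bfar in KO over WT, and 0.42 for glycolysis and -0.34 for naive and memory genes in Aged over Young, and shrinks ratios by construction.

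Leiden resolution 0.5 put 98.2% of KO and 94.4% of WT cells in the CD8 T-like class, and the stricter cell filter 89.7% of Young cells. Counted by cells, the V beta effective number was 8.61 in Aged and 10.04 in Young. CPM without mitochondrial and ribosomal protein genes, the looser filter, no doublet removal and removal of the cells with the highest Scrublet scores moved none of the results that answer a comparison beyond its interval. No doublet removal put back only the 1 marked Young cell, so its lack of change was nearly fixed in advance. Depth limits the shares of cells, which were given with and without thinning for that reason.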

Other observations

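Il17a, the gene of the cytokine interleukin 17A, led a T cell cluster of the KO and WT libraries together with Il17f and Il22. The cluster held 4.48% of KO and 4.37% of WT CD8 T-like cells. When all kept cells were clustered, the cluster led by these 3 genes entered the class on a tie. It had 1 marker of the class and 1 of gamma-delta T cells among its 10 leading genes. Its CD8 level was 814 CPM, against 783 to 2007 CPM in the other clusters of the class. These cells may therefore be gamma-delta T cells, which was not tested. Il17a had 1175 UMIs in 178 KO cells and 1012 UMIs in 171 WT cells, of which 169 and 164 were CD8 T-like. In the transfer experiment it had 0 UMIs in Aged and 38 UMIs in 8 cells in Young. The pairs differ in kit and in hosts, so this difference between them was not tested.

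Uneven V beta usage was not limited to the granzyme cluster of the Aged library. In Young, the same cluster held 567 cells, and 70.9% (66.9 to 74.7) of its 533 cells with a segment carried Trbv19. Its median depth was 9422 UMIs, against 15324.5 UMIs in Aged, and Gzmf stood at 56.4 CPM there against 1574 CPM in Aged. A cluster led by Gstm5 and Tnfsf11 carried Trbv26 in 53.9% of its Young cells with a segment and Trbv1 in 32.0% of its Aged cells with a segment. Receptor segments were left out of the clustering, so these shares are not set by it, while the granzymes helped to define their cluster. All genes of this part were chosen after their values were seen.

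A small cluster inside the CD8 T-like class of the Aged and Young libraries, 20 and 48 cells, was led by genes of antigen-presenting cells (H2-Aa, Il1b and Lyz2). The Y chromosome gene Ddx3y was seen in 29.2% of Aged and 22.7% of Young cells, which held 7 and 0 UMIs of Xist.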
